A study of Mus musculus with 12 samples.

How the data were processed

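The samples were 12 mouse embryos at 8.5 days post coitum, each hybridised to 1 array of an Illumina mouse BeadChip read in 1 colour. Per the labels' protocols, heterozygous Cited2 females of the C57BL6/J strain received a high-fat or a control diet from 6 weeks of age. After 8 weeks they were mated to heterozygous males, and the diet went on during pregnancy. Also per the labels' protocols, the yolk sac and allantois were taken off each embryo, somites were counted to match stages, and total RNA was purified with RNeasy Micro columns, checked on a Bioanalyser and labelled with biotin. The labels give 4 groups of 3 embryos, namely wild-type and Cited2 knockout embryos of mothers on the control diet and on the high-fat diet. They mark the samples of a group as separate embryos. The sample titles hold 6 numbers, each shared by 1 knockout and 1 wild-type embryo on the same diet. What these numbers mark is not stated. Whether embryos shared a litter, the sex of the embryos and the slide of each array are not given in the sources used here.

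The deposited single-array tables and the deposited table of the whole series held 3 kinds of values per probe. The deposited average signal was a bead intensity on a linear scale, negative at some probes, and the authors exported it from BeadStudio version 3.2.6, per the submitters' processing notes. The deposited detection p-value gave each probe's standing against the negative control beads, and the standard deviation over beads was deposited as an intensity too. In the deposited single-array tables the detection score was a fraction, which equalled 1 minus the detection p-value of the series table. The number of beads per probe was deposited beside them, per the file headers. Signals in the series table differed by at most 0 from those in the single-array tables. Per-sample columns of other series numbered 0. The authors' own table of processed values held log2 values with 1 column per array. Each of its columns had a rank correlation of 1 with its own array's signal and of at most 0.949 with any other array, so scale and direction were known, while its normalization method is not given in the sources used here. The column medians of the authors' table were 4.98, 5.03 and 5.00 for control-diet knockout replicates 1 to 3, and 5.01, 5.02 and 5.00 for the high-fat knockout replicates. They were 4.97, 5.00 and 5.01 for control-diet wild-type replicates 1 to 3, and 4.99, 5.00 and 5.00 for the high-fat wild-type replicates.

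Signals were background-corrected and quantile-normalized with the neqc function of limma 3.58.1 in R 4.3.3, which took the background from the detection p-values and added an offset of 16. Of 45281 probes, 19595 with a detection p-value under 0.01 on at least 3 of the 12 arrays were tested. Between 16584 and 18853 probes were detected per array, which is 36.6% to 41.6% of them. The number of arrays limits the precision. Probe annotation came from the platform table that came with the data, which gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Gene IDs of 34807 of the probes with 1 symbol matched the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and also gave the order of neighbouring genes. A probe with no symbol or several was counted and not named. A gene with several tested probes was taken at the probe with the highest mean log2 signal, and other probes were compared with it. The tested probes with a symbol numbered 16537 and stood for 10764 genes.

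All 12 embryos entered 1 linear model with a mean per group, fitted with limma's lmFit and eBayes, so that the 4 groups shared an estimate of the spread. The 7 comparisons were the genotype effect averaged over diets, the diet effect averaged over genotypes, the genotype effect on each diet, the diet effect in each genotype, and the interaction. P-values were adjusted over the tested probes by the Benjamini-Hochberg method, with a threshold of 0.05. All errors of log2 differences are standard errors of this model. Where a probe was undetected on every array of a group, its fold is given as a bound. The brighter group's mean was then set against the dim group's mean of, per array, the higher of the lowest normalized signal among detected probes and the dim probe's own signal. Where only some arrays of the dim group detected a probe that passed in a genotype effect, those entered this bound with their own signal, a step added after the data had been seen.

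The samples, the model, the rule for naming genes and, except where stated below, the alternatives were chosen before the data were examined. Cited2 and 4 left-right patterning genes were named in every comparison. Of these 4, 3 had a tested probe and 1 was not analysed here. For the averaged effects the rule took up to 12 genes with the highest and 12 with the lowest log2 fold change among those that passed, and for the other comparisons up to 5 and 5. Where no gene other than Cited2 passed, it took the 5 with the smallest p-values. For each gene list that passed in an averaged effect it took up to 4 members with the smallest p-values.

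Before the data were examined, 45 lists with 1278 entries were also written from general knowledge, covering tissues and cell types of the embryo, tissues outside it, signalling pathways, metabolism and stress. No gene was found for 3 entries. Lists with at least 5 tested genes were tested with limma's camera at its preset correlation between genes of 0.01, and again with an estimated correlation. Both were adjusted over the 45 lists of a comparison. In data simulated without any change in the lists, the preset correlation passed a median of 4.5 and at most 12 of the 45 lists over 20 draws, and the estimated correlation passed 0. The list of paraxial mesoderm and somites, shifted by 0.5 on the log2 scale, was recovered in 20 of 20 draws under either setting. Recovery of the other lists, whose genes may be more strongly correlated, was not simulated. A list that failed with an estimated correlation may therefore still be shifted. List means per embryo were taken after centring each gene on its mean over the 12 embryos, and were compared with two-sided exact permutation tests over 924 splits.

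The model was tested on simulated data in which 200 of the 19595 probes were changed. In the genotype effect averaged over diets, 31.0% of the probes changed by 0.5 on the log2 scale, 86.0% of those changed by 1 and 97.6% of those changed by 2 were recovered. The shares for the averaged diet effect were 30.1%, 84.5% and 97.0%. For the genotype effect on the control diet they were 7.46%, 62.4% and 93.0%, on the high-fat diet 7.46%, 54.0% and 90.3%. For the diet effect in wild-type embryos they were 6.27%, 53.7% and 90.6%, in knockout embryos 7.46%, 59.4% and 93.3%. For the interaction they were 0.597%, 19.7% and 75.5%. The noise was drawn independently for each probe, so correlation between probes and batches of arrays were not simulated. The adjustment is also stricter where fewer than 200 probes change. The shares may therefore be higher than in the real data.

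Arrays were examined for batches by the median coefficient of variation over beads of probes with a signal of at least 500 and by principal components. The alternatives planned before the data were examined were no background correction, median scaling, cyclic loess, the authors' table, no filter, a filter on detection on all 12 arrays, array weights, an intensity trend with robust variances, blocks by the numbers in the sample titles or by replicate number, the signal of a Y-linked probe as a covariate, a fit of the compared groups alone, the mean of all probes of a gene for the lists, and leaving out each embryo in turn. Leaving out an embryo leaves at least 2 in each group. A block by array set, a covariate for bead variation, their combinations with weights and replicate blocks, and lists without 1 embryo were added after the data had been seen. Figures were drawn with matplotlib 3.10.9, and tables for them were read with pandas 2.3.3 under Python 3.11.15.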

Results

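Transcripts were measured on 12 arrays, each of 1 whole mouse embryo at 8.5 days post coitum. The embryos fell into 4 groups of 3 by genotype, wild type or Cited2 knockout, and by the mother's diet, control or high-fat. Between 16584 and 18853 of the 45281 probes were detected per array, and 19595 probes were tested. Correlations between arrays lay between 0.953 and 0.993.

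The 12 arrays formed 2 sets of 6 that the groups did not explain. Set A held replicate 1 of each group and replicate 2 of the high-fat groups, and set B held the rest. The sets also followed the order in which the samples are listed, set A being the first 6 and set B the last 6. Whether they were processed as 2 batches is not given in the sources used here. The median coefficient of variation between beads of a probe was 18.0% to 20.5% in set A and 21.4% to 23.8% in set B. The first principal component held 47.7% of the variance and ran from −43.0 to −17.5 in set A and from 16.1 to 48.7 in set B. The sets were divided at the largest gap in this coefficient (0.967 points, the next largest 0.880). As a description of the sets and not as a test of them, 4738 probes differed in limma, 2734 higher and 2004 lower in set B. Each set held 3 knockout and 3 wild-type arrays. High-fat arrays numbered 4 in set A and 2 in set B, so diet and set overlapped in part. Values with the set as a block and within each set are therefore given beside many of the results. The sets were found after the data had been seen.

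**Figure D1:**
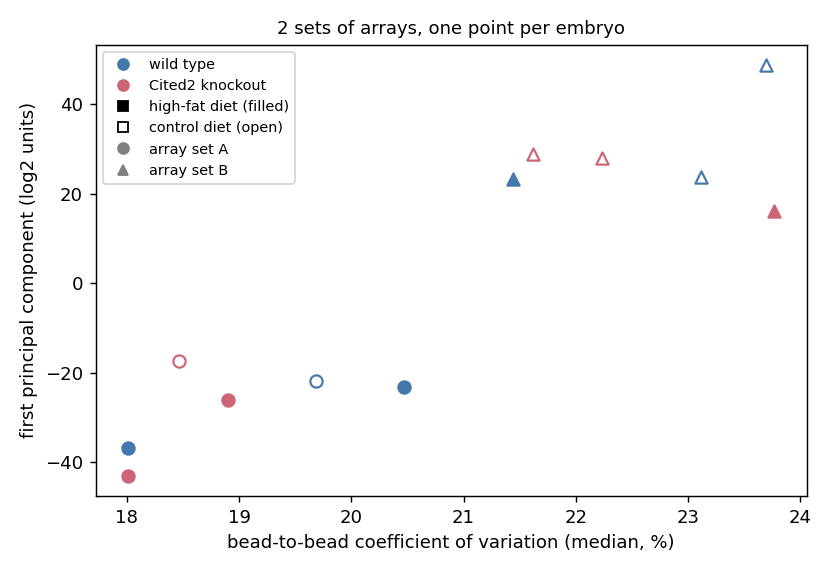
Median coefficient of variation between beads (percent, horizontal) against the first principal component (vertical) for the 12 arrays, coloured by genotype, with filled symbols for the high-fat diet. Set A lies at 18.0% to 20.5% and negative component values, and set B at 21.4% to 23.8% and positive values.

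The first comparison asked how loss of Cited2, a transcriptional co-regulator that binds CBP and p300, changed the embryo's transcripts. At the brightest of its 3 tested probes (ILMN_2477221), the Cited2 signal was 9.4, 6 and 10 in control-diet knockout replicates 1 to 3, and −3.5, 4.4 and 119.7 in the high-fat knockout replicates. In wild-type replicates 1 to 3 it was 2626.8, 2907.2 and 4210.3 on the control diet and 1615.5, 1898 and 3606.8 on the high-fat diet. The probe was detected in 6 of 6 wild-type embryos and 1 of 6 knockout embryos, which was high-fat replicate 3. On the log2 scale, Cited2 averaged 4.99 ± 0.92 in knockout and 11.40 ± 0.34 in wild-type embryos (SD, n = 6). It was lower by a log2 fold change of −6.41 ± 0.35 averaged over diets (limma, adjusted p = 4.6e-06), at least 60.3-fold with undetected arrays set to the detection floor, with −6.56 in array set A and −5.88 in set B. The other Cited2 probes gave −3.76 ± 0.16 and −3.90 ± 0.16 (adjusted p = 2.74e-07 for each), the former at least 10.6-fold lower with 1 of 6 knockout arrays detecting it and the latter at least 8.83-fold lower because 0 of 6 knockout arrays detected it. Where the 3 probes lie relative to the deleted part is not given in the sources used here.

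Averaged over diets, 14 probes passed, 5 higher and 9 lower in knockout embryos, which stood for 10 named genes and 2 probes without a gene name. An unadjusted p under 0.05 was found for 656 probes, where 980 would be expected by chance, and for 1100 with the array set as a block. Lats1, a kinase of the Hippo pathway, rose from 4.67 ± 0.08 in wild-type to 5.92 ± 0.28 in knockout embryos (log2 signal, SD, n = 6). Its log2 fold change was 1.25 ± 0.13, and it was at least 1.64-fold higher because wild-type arrays did not detect it (adjusted p = 0.00184). Adat2, a subunit of the tRNA adenosine deaminase, rose by 1.02 ± 0.10, from 10.13 ± 0.11 to 11.14 ± 0.23 (adjusted p = 0.00135). Csmd3, a large transmembrane protein with CUB and sushi domains, rose by 0.71 ± 0.09, at least 1.07-fold (adjusted p = 0.0125). Log2 fold changes within array sets A and B were 1.37 and 1.17 for Lats1, 0.91 and 1.15 for Adat2, and 0.66 and 0.81 for Csmd3.

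The genes that fell included developmental regulators. En2, a homeobox gene of the midbrain and hindbrain, fell by 1.98 ± 0.21 on the log2 scale, from 7.02 ± 0.66 in wild-type to 5.04 ± 0.57 in knockout embryos (adjusted p = 0.00184), at least 3.10-fold, as 3 of 6 knockout arrays detected it. Meox1, a homeobox gene of the somites, fell by 0.69 ± 0.10, from 10.36 ± 0.14 to 9.68 ± 0.14 (adjusted p = 0.0211). Cldn10, a tight junction protein, fell by 0.86 ± 0.10 (adjusted p = 0.00584). Hebp2, a haem-binding protein, fell by 1.18 ± 0.11, from 7.17 ± 0.15 to 5.99 ± 0.25 (adjusted p = 0.000783), although its other tested probe gave 0.05. The uncharacterised transcript E030030I06Rik fell by 2.00 ± 0.21, from 7.36 ± 0.47 to 5.36 ± 0.26 (adjusted p = 0.00184), at least 3.90-fold, as 4 of 6 knockout arrays detected it, and its other tested probes gave −0.88 (adjusted p = 0.103) and −0.79 (0.0786). Flrt1, a leucine-rich transmembrane protein, passed at its dimmer probe, with −1.05 ± 0.13 and at least 1.63-fold lower (adjusted p = 0.00855), while its brightest probe gave −1.31 and an adjusted p of 0.0619. The values in sets A and B were −1.64 and −2.37 for En2, −0.61 and −0.74 for Meox1, −0.84 and −0.90 for Cldn10, −1.14 and −1.19 for Hebp2, −2.35 and −1.45 for E030030I06Rik, and −1.05 and −1.05 for the dimmer Flrt1 probe. The 2 unnamed probes were higher, ILMN_1239542 by 2.92 ± 0.36 (adjusted p = 0.00674) and ILMN_2645333 by 1.08 ± 0.14 (adjusted p = 0.00855, at least 1.55-fold). In wild-type high-fat replicate 3 ILMN_1239542 was at 6.69, against 4.24 to 4.35 in the other wild-type and 7.10 to 7.96 in the knockout embryos, and it was detected in this 1 of 6 wild-type embryos (at least 4.43-fold higher in knockout embryos). Its log2 fold change was 3.41 in set A and 1.88 in set B.

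**Figure D2:**
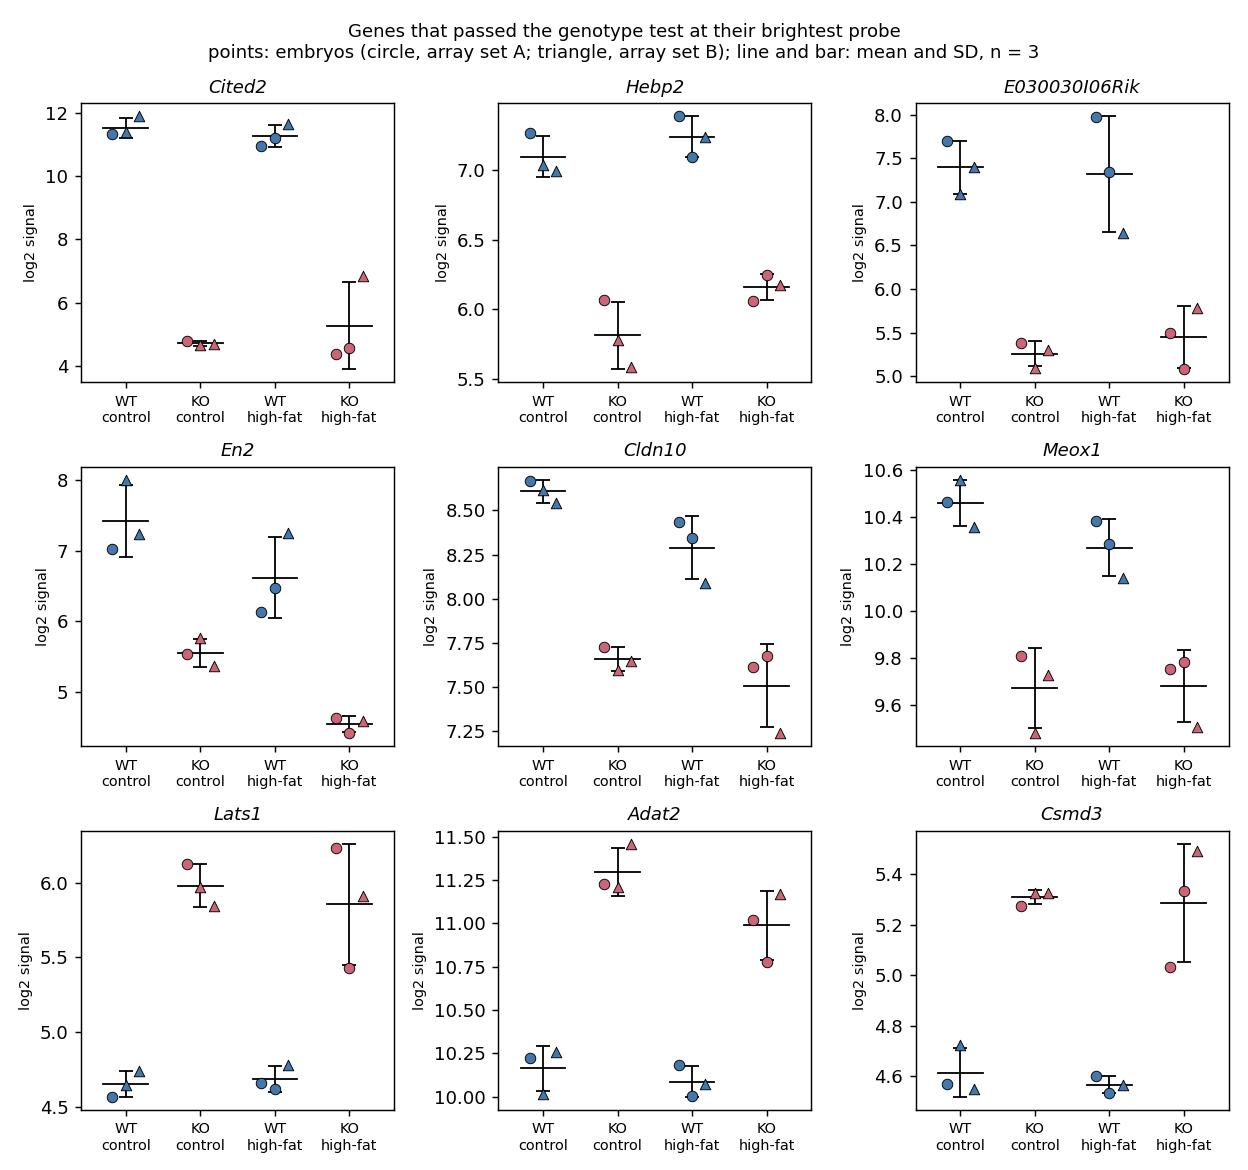
Normalized log2 signal (vertical) of Cited2 and 8 genes that passed in the averaged genotype comparison, per embryo in the 4 groups (horizontal), with circles for array set A, triangles for set B, and a line and bar for the mean and SD of 3 embryos. The Cited2 value of knockout high-fat replicate 3 stands above those of the other 5 knockout embryos.

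A block for array set raised the count to 27 probes, 8 higher and 19 lower, and all 14 were among them. Array weights gave 120 probes, and 30 together with the array set, while 4 passed among probes detected on all 12 arrays. The split was 4 higher and 16 lower with median scaling. The Meox1 call was lost without knockout high-fat replicate 2 (adjusted p = 0.0532), wild-type high-fat replicate 1 (0.0838) or 2 (0.102), wild-type control replicate 1 (0.0756) or 2 (0.0961), knockout control replicate 2 (0.0818) or 3 (0.0656), or knockout high-fat replicate 3 (0.0685). The Csmd3 call was lost without knockout high-fat replicate 2 (adjusted p = 0.0547), wild-type control replicate 1 (0.0560), wild-type high-fat replicate 2 (0.0676), or knockout control replicate 2 (0.0632) or 3 (0.0545), and with median scaling (0.0515). With the Y-linked covariate Meox1 and Csmd3 each had an adjusted p of 0.0549, and without background correction Flrt1 had 0.0563 at its dimmer probe. A fixed block by title number ended the calls of Lats1 (adjusted p = 0.0673), Hebp2 (0.0523), Cldn10 (0.257), Csmd3 (0.238), Meox1 (0.400) and Flrt1 at its dimmer probe (0.264). With the array set in that block as well, those of Meox1 and Csmd3 were lost.

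Genes beside Cited2 were frequent among the genes that passed. Among 10562 tested protein-coding genes other than Cited2, 9 had passed, and 4 of these lay among the 46 tested genes within 50 protein-coding genes on either side of Cited2 (one-sided Fisher's exact p = 3.9e-08). Counted in protein-coding genes from Cited2, Adat2 lay 7 and Lats1 32 away on one side, and Hebp2 8 and E030030I06Rik 31 away on the other. The median log2 fold change of the 46 genes was −0.05. Blocking by array set, 6 of 15 genes lay in this window (Fisher's exact p = 2.36e-11), the additions being Rab32, 21 away, and Sash1, 25 away. The window was set after the values were seen.

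**Figure D3:**
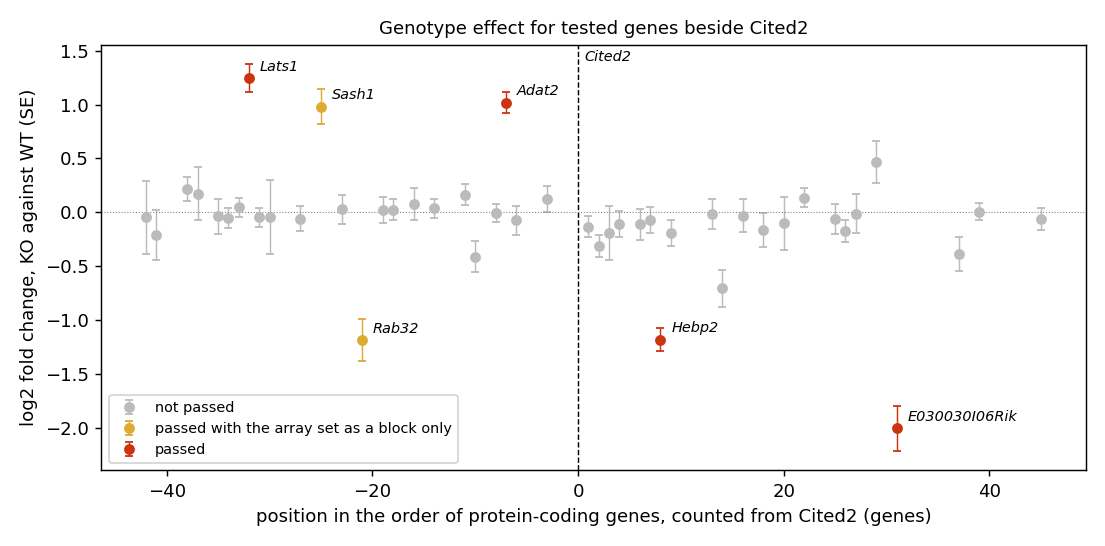
Log2 fold change between knockout and wild-type embryos with its standard error (vertical) against position in the order of protein-coding genes counted from Cited2 (horizontal). Red points passed, yellow points passed only with the array set as a block, and grey points did not pass. The 4 red points are Adat2 and Lats1, above 0, and Hebp2 and E030030I06Rik, below 0.

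Somite genes fell together in knockout embryos. Of 13 tested genes of the paraxial mesoderm and somite list, 12 had a negative log2 fold change, with a mean of −0.28 (camera, adjusted p = 3.15e-08; adjusted p = 0.0366 with an estimated correlation). Meox1 was the member that passed over all probes, and 4 members were lower adjusted over the list alone. Uncx, which patterns the posterior part of each somite, gave −0.96 (adjusted p = 0.0607), Tcf15 −0.67 (0.527) and Foxc2 −0.42 (0.752). The list mean per embryo was −0.14 ± 0.13 in knockout and 0.14 ± 0.08 in wild-type embryos (SD, n = 6), and every wild-type embryo lay above every knockout embryo (exact permutation p = 0.00216, the smallest that 924 splits can give, adjusted p = 0.0325). The shift was −0.31 in array set A and −0.21 in set B, and −0.28 with the set as a block, where the adjusted p with an estimated correlation was 0.109.

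The neural tube and brain list shifted by a mean of −0.30 over 25 genes, 20 of them negative (adjusted p = 5.04e-07; adjusted p = 0.229 with an estimated correlation). En2 passed over all probes, and 5 members were lower adjusted over the list alone. En1 gave −1.36 (adjusted p = 0.120), Nkx2-2 −0.63 (0.752) and Wnt8b −0.61 (0.949). The cardiac muscle list shifted by −0.35 over 27 genes, 23 negative (adjusted p = 3.15e-08; adjusted p = 0.259 with an estimated correlation), with 0 members passing over all probes in limma and 2 lower adjusted over the list alone. Its ventricular myosin light chain gene Myl2 gave −1.71 (adjusted p = 0.206), 9.20 ± 1.17 in knockout against 10.92 ± 0.47 in wild-type embryos (SD, n = 6), and Hspb7 gave −0.70 (0.597), Actc1 −0.53 and Myh6 −0.65 (1.00 for each). The cardiac shift was −0.04 in array set A and −0.70 in set B, and the neural tube shift −0.21 and −0.45. Over the list means of the 12 embryos the exact permutation p was 0.123 for cardiac muscle (adjusted p = 0.517) and 0.0130 for neural tube and brain (adjusted p = 0.146).

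Visceral endoderm markers of the yolk sac shifted the opposite way, with a mean of 0.62 over 25 genes, 24 of them positive (adjusted p = 2.62e-10; adjusted p = 0.347 with an estimated correlation). None of the members passed in limma, over all probes or adjusted over the list alone. The list mean was 0.31 ± 0.79 in knockout and −0.31 ± 0.69 in wild-type embryos (SD, n = 6; exact permutation p = 0.173), with shifts of 0.02 in array set A and 1.64 in set B. Without knockout high-fat replicate 3 the shift was 0.37. Members gave 0.30 for Lrp2, 0.45 for Dab2, 0.43 for Tmprss2 and 0.48 for Mttp (adjusted p = 1.00 for each). Over the 12 embryos, as deviations from the group means, this list mean ran against those of the cardiac list (r = −0.841, permutation p = 0.00073, adjusted p = 0.00219; rho = −0.783, p = 0.00401) and of the neural tube list (r = −0.815, permutation p = 0.00147, adjusted p = 0.00294; rho = −0.713, p = 0.0117). Without the 2 embryos farthest from the median, r was −0.768 and −0.713. It was, within sets A and B, −0.864 and −0.831 for the cardiac list and −0.820 and −0.772 for the neural tube list. In all, 6 such relations were computed, and the trophoblast list gave r = 0.545 (permutation test, adjusted p = 0.0782). These relations were chosen after the list shifts had been seen. Their permutation tests treat the 12 deviations as independent, although deviations within a group cancel out, so the p-values may be too small.

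**Figure D4:**
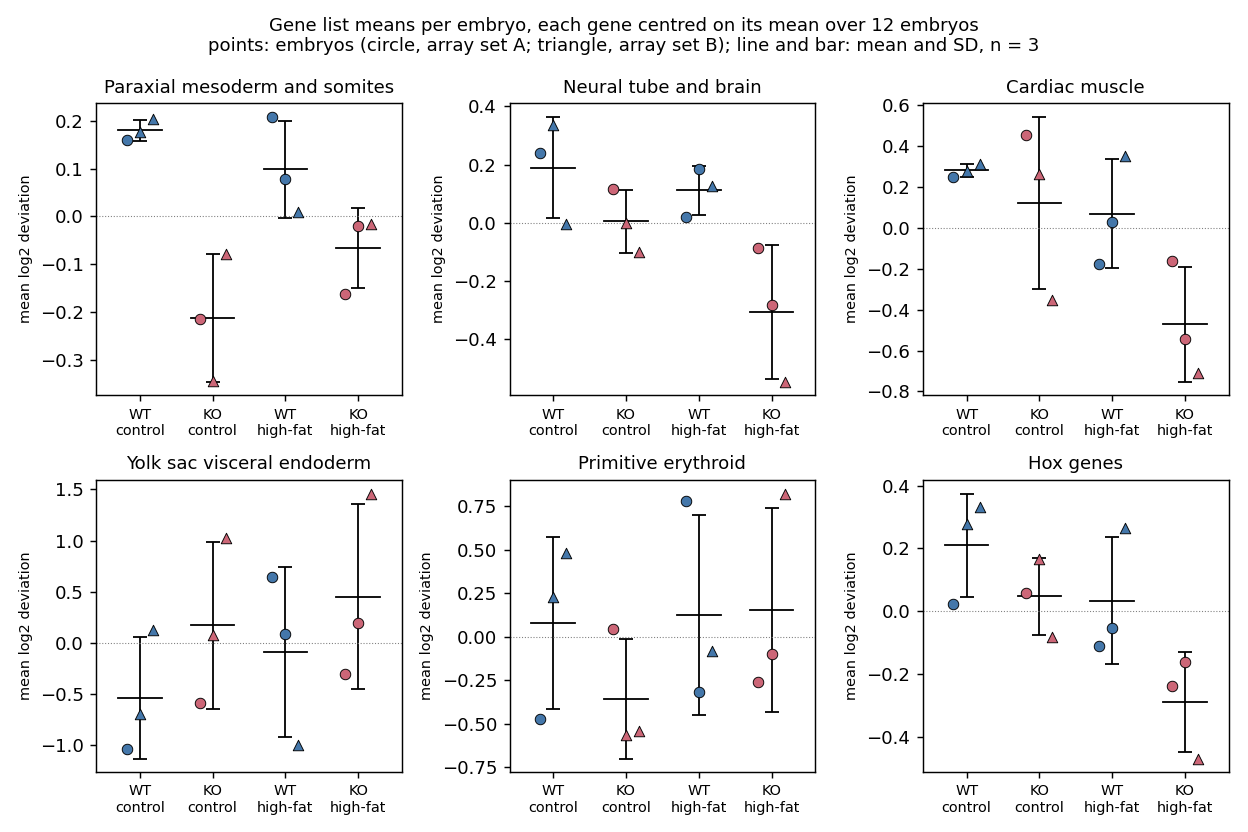
Mean log2 deviation (vertical) of the members of 6 gene lists per embryo in the 4 groups (horizontal), each gene centred on its mean over the 12 embryos, with circles for array set A, triangles for set B, and a line and bar for the mean and SD of 3 embryos. Somite values separate the genotypes, and the yolk sac list rises where the cardiac and neural tube lists fall.

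Averaged over diets, 14 of 45 lists passed at the preset correlation, 6 shifted up and 8 down, and the somite list alone passed with an estimated correlation. In the data simulated without any change in the lists, up to 12 passed at the preset correlation. Also shifted down were neural crest (mean −0.27, 13 of 18 genes negative, adjusted p = 2.67e-05), Hox genes (−0.24, 16 of 22, 5.13e-05) and primitive streak and tailbud (−0.09, 12 of 17, 0.00323), with an adjusted p of 0.229 each with an estimated correlation. Endothelium (−0.12, 22 of 27, 0.000791) and hypoxia targets of HIF1 (−0.11, 21 of 27, 0.00136) had adjusted p = 0.362 and 0.243 with an estimated correlation. Their leading members did not pass, such as Crabp1 with −0.37, Hoxa9 with −0.95, Fgf8 with −0.39, Emcn with −0.66 and Egln1 with −0.51. Shifted up were gut endoderm (mean 0.19, 15 of 19 genes positive, adjusted p = 0.00049) and lipid uptake and transport (0.24, 11 of 16, 0.00594), with an adjusted p of 0.229 each with an estimated correlation. Cholesterol synthesis (0.10, 15 of 19, 0.0239), p53 targets (0.09, 11 of 15, 0.0217) and interferon response (0.09, 12 of 14, 0.0333) had adjusted p = 0.597, 0.310 and 0.460 with an estimated correlation. Trh gave 0.80, Fabp3 0.37, Srebf2 0.28, Phlda3 0.40 and Ifitm3 0.26, none of which passed. The gut endoderm and hypoxia lists also held members with the opposite sign, such as Pyy with −0.89 and Ddit4 with 0.45. The lipid list shares 5 genes with the yolk sac list, and its mean followed that list over the embryos (r = 0.996). The gut endoderm list shares 2, and its mean ran with that list too (r = 0.758, permutation test, adjusted p = 0.00612, rho = 0.692). Within sets A and B its r was 0.731 and 0.825. Adjusted over the list alone, 2 gut endoderm genes were higher and 1 lower, 1 streak gene and 1 hypoxia gene were lower, and 0 passed in the other 7 of these lists. Shifts within sets A and B were −0.06 and −0.47 for neural crest, −0.04 and −0.50 for Hox genes, 0.03 and 0.33 for gut endoderm, and 0.02 and 0.60 for lipid uptake. They were −0.14 and −0.03 for streak and tailbud, −0.003 and −0.23 for endothelium, and −0.05 and −0.20 for hypoxia targets. Cholesterol synthesis gave −0.02 and 0.09, p53 targets 0.009 and 0.18, and interferon response 0.007 and 0.16. Cholesterol synthesis was thus not higher in set A. Neural crest and Hox genes each had an exact permutation p of 0.0714 (adjusted p = 0.517). That p was 0.113 for gut endoderm and for p53 targets, 0.136 for endothelium, 0.147 for lipid uptake and 0.149 for hypoxia targets (adjusted p = 0.517 for each). For interferon response it was 0.258 (adjusted p = 0.722), for streak and tailbud 0.351 and for cholesterol synthesis 0.413 (adjusted p = 0.760 for both). All 14 lists passed with the array set as a block. Without knockout high-fat replicate 3, the calls of lipid uptake (adjusted p = 0.105) and p53 targets (0.0820) were lost. With the Y-linked covariate 6 of the 14 calls were lost, with an adjusted p of 0.0789 for both streak and Hox genes, 0.222 for endothelium, 0.308 for hypoxia targets, 0.436 for cholesterol synthesis and 0.523 for interferon response. Single embryos moved several shifts by more than 1.5 times. Without knockout control replicate 3 the shift was 0.02 for cholesterol synthesis, −0.07 for endothelium, −0.23 for cardiac muscle and −0.14 for the streak and tailbud, which gave −0.03 without knockout high-fat replicate 1. Hypoxia targets gave −0.06 and p53 targets 0.06 without wild-type high-fat replicate 3, and lipid uptake 0.15 without knockout high-fat replicate 3.

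Left-right signalling genes, fixed for naming because Cited2 acts in left-right patterning, did not pass in the main model. Lefty1, an antagonist of Nodal signalling, gave 1.76 ± 0.43 (adjusted p = 0.597), with 6.60 ± 1.34 in knockout and 4.83 ± 0.32 in wild-type embryos (SD, n = 6), and 1.70 and 1.46 in array sets A and B. Array weights called it, with 2.33 (adjusted p = 0.0149), and weights together with the array set gave an adjusted p of 0.155. Its relative Lefty2 gave −1.24 ± 0.66 and the ligand Nodal 0.71 ± 0.52 (adjusted p = 1.00 for each). In sets A and B these were −2.89 and 0.20 for Lefty2 and −0.47 and 1.5 for Nodal. The left-right list of 21 genes had a mean of 0.08 and a median of −0.02 (adjusted p = 0.866).

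On the control diet, Cited2 fell in knockout embryos by 6.82 ± 0.50 on the log2 scale (adjusted p = 0.000109), at least 83.0-fold. Lats1 rose by 1.33 ± 0.18, from 4.65 ± 0.09 to 5.98 ± 0.14 (SD, n = 3; adjusted p = 0.0351; at least 1.78-fold), and Adat2 by 1.13 ± 0.14 (0.0157). E030030I06Rik fell by 2.14 ± 0.30 (adjusted p = 0.0358; at least 4.31-fold, with 2 of 3 knockout arrays detecting it), Hebp2 by 1.28 ± 0.15 (0.0122) and Flrt1, at its dimmer probe, by 1.28 ± 0.19 (0.0495; at least 2.13-fold). These genes and Cited2 made up the 8 probes that passed, 2 higher and 6 lower. Median scaling gave 1 higher and 7 lower, and array weights gave 16 probes. Blocking by array set, 17 probes passed, and the 8 were among them. Set A holds 1 embryo of each of these groups. Log2 fold changes in sets A and B were 1.56 and 1.21 for Lats1, 1.01 and 1.2 for Adat2, −2.32 and −2.04 for E030030I06Rik, −1.19 and −1.33 for Hebp2, and −1.30 and −1.27 for Flrt1.

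Each of these calls other than Cited2 was lost when any 1 of several embryos was left out, so the losses single out no embryo. The log2 fold changes moved less than the calls. Where a call was lost without a control-diet embryo, Lats1 gave 1.25 to 1.40, Adat2 1.05 to 1.18 and E030030I06Rik −2.29 to −1.98. In the same fits Hebp2 gave −1.33 to −1.17 and Flrt1, at its dimmer probe, −1.30 to −1.25. Only the 3 Cited2 probes passed without control-diet wild-type replicate 1, 2 or 3 or without knockout replicate 2 or 3, where the adjusted p of Hebp2 was 0.0814, 0.0785, 0.0515, 0.0775 and 0.0887. That of Adat2 was 0.0814, 0.121, 0.0616, 0.0775 and 0.123, and those of Lats1, E030030I06Rik and Flrt1 were higher than for Hebp2 in each case. Without knockout control replicate 1, 4 probes passed, those of Cited2 and Hebp2, and the adjusted p of Adat2 was 0.0763. Omitting a high-fat embryo, which only shares the spread, ended calls too. Without wild-type high-fat replicate 2, 5 probes passed and Lats1, E030030I06Rik and Flrt1 had adjusted p = 0.0753. Lats1 had 0.0510 without wild-type high-fat replicate 1 and 0.0502 without knockout high-fat replicate 3, and E030030I06Rik had 0.0776 without knockout high-fat replicate 1. Flrt1 had 0.0903 and 0.0502 without knockout high-fat replicates 1 and 3. Processing ended calls as well, such as Adat2 with median scaling (adjusted p = 0.312), Adat2 and Hebp2 in a fit of the 6 compared embryos (0.157 for each), Lats1 and E030030I06Rik without a filter on detection (0.0967 and 0.188) and Flrt1 without background correction (0.358).

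Among the lists on the control diet, somite genes fell by a mean of 0.39, 11 of 13 negative (adjusted p = 9.54e-13; adjusted p = 0.00765 with an estimated correlation). In all 13 lists passed, 5 up and 8 down, and the somite list alone passed with an estimated correlation. Yolk sac endoderm gave 0.71, 24 of 25 positive (adjusted p = 3.99e-09; adjusted p = 0.423 with an estimated correlation), and primitive erythroid genes −0.43, 17 of 19 negative (0.0042; adjusted p = 0.484 with an estimated correlation). Cholesterol synthesis gave 0.21, 17 of 19 positive (adjusted p = 8.64e-05; adjusted p = 0.348 with an estimated correlation). Adjusted over the list alone, 2 somite genes were lower and 0 members of the other 3 lists passed. Single embryos weighed on the shifts of these 3 lists. Cholesterol synthesis means were −0.056, −0.004 and 0.487 in control-diet knockout replicates 1 to 3, against −0.07 ± 0.12 in the wild type (SD, n = 3). Yolk sac means were −0.59, 0.075 and 1.03, against −1.03, −0.69 and 0.12 in wild-type replicates 1 to 3. Erythroid means were 0.04, −0.57 and −0.55, against −0.47, 0.23 and 0.48. The list of CITED proteins and their partners, which contains Cited2, gave a mean of −0.48 and a median of −0.09 (adjusted p = 0.0231; adjusted p = 0.254 with an estimated correlation). The Y-linked covariate ended its call (adjusted p = 0.0522) and those of cardiac muscle (0.792) and Hox genes (0.201). Lefty1, Lefty2 and Nodal gave 1.14, 0.18 and 0.82 (adjusted p = 1.00 for each).

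On the high-fat diet, Cited2 fell in knockout embryos by 5.99 ± 0.50 (adjusted p = 0.000449), at least 43.9-fold, with 1 of 3 knockout arrays detecting it, and its 3 probes were those that passed. In a fit of the 6 compared embryos the brightest Cited2 probe had an adjusted p of 0.0948. The 5 genes with the next smallest p-values did not pass. They were En2 with −2.08 ± 0.29 (adjusted p = 0.0550, at least 2.62-fold lower), Hebp2 with −1.08 ± 0.15 (0.0550), Lats1 with 1.17 ± 0.18 (0.104, at least 1.5-fold higher), Adat2 with 0.90 ± 0.14 (0.104) and E030030I06Rik with −1.87 ± 0.30 (0.112). En2 was at 4.54 ± 0.12 in knockout and 6.62 ± 0.57 in wild-type embryos (SD, n = 3). Array weights gave 1325 probes, and 8 together with the array set. With the array set as a block 6 probes passed, and adjusted p-values were 0.00992 for En2 and 0.0161 for Hebp2, over ranges of 0.000303 to 0.337 and 0.00158 to 0.728 across the alternatives. Within sets A and B, with 1 embryo per group in set B, En2 gave −1.78 and −2.67 and Hebp2 −1.08 and −1.06.

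Calls on the high-fat diet also changed when single embryos were left out. Probes that passed numbered 5 without knockout high-fat replicate 1, 8 without knockout control replicate 3 and 6 without wild-type high-fat replicate 3. En2 passed without wild-type high-fat replicate 1 (adjusted p = 0.0455) or wild-type control replicate 2 (0.0268), and Hebp2 without knockout control replicate 1 (0.0439) or 3 (0.0453). Lats1 passed without knockout high-fat replicate 2 (adjusted p = 0.0143) and E030030I06Rik without wild-type high-fat replicate 3 (0.0127). Lefty1 gave 2.39 ± 0.61 (adjusted p = 0.723), Lefty2 −2.66 ± 0.93 and Nodal 0.61 (1.00 for each), while array weights called Lefty1 with 3.55 (0.00269) and Lefty2 with −2.71 (0.0217).

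Lists that passed on the high-fat diet numbered 11, 3 up and 8 down, and 0 in limma's camera with an estimated correlation, where adjusted p-values were 0.358 to 0.631. Cardiac muscle gave −0.54, 24 of 27 negative (adjusted p = 3.35e-09; adjusted p = 0.425 with an estimated correlation). Neural tube and brain gave −0.42, 19 of 25 negative (3.57e-06), and neural crest −0.43, 13 of 18 negative (2.62e-05), each with an adjusted p of 0.358 with an estimated correlation. Adjusted over the list alone, 2 cardiac, 5 neural tube and 4 neural crest genes were lower. Yolk sac endoderm gave 0.54, 24 of 25 positive (adjusted p = 4.08e-05; adjusted p = 0.631 with an estimated correlation). Without knockout high-fat replicate 3, 5 lists passed, and the yolk sac list had an adjusted p of 0.967. The Y-linked covariate ended the calls of Hox genes (adjusted p = 0.228), endothelium (0.141), maternal decidua (0.251), hypoxia targets (0.0504) and interferon response (0.349).

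The averaged diet comparison asked how the mother's high-fat diet changed the embryo's transcripts. In limma, 0 probes passed, while 2314 had an unadjusted p under 0.05 where 980 would be expected by chance, and the smallest adjusted p was 0.309. The 5 genes with the smallest p-values, which did not pass, were Zfp507 with −1.0 ± 0.15, Vrtn, a gene linked to vertebral number, with 1.35 ± 0.24, Tob1 with −0.72 ± 0.13, the retinoic acid binding protein gene Crabp1 with −0.69 ± 0.12, and Nckap1l with 0.75 ± 0.13. Vrtn was at 6.75 ± 0.62 in high-fat and 5.40 ± 0.39 in control embryos (SD, n = 6), and Zfp507 at 6.37 ± 0.28 and 7.37 ± 0.36. With the array set as a block, 0 probes passed in limma, 1978 had an unadjusted p under 0.05 and the smallest adjusted p was 0.282. Array weights called 6128 probes, among them these 5 genes (adjusted p = 0.00596 to 0.00759), and 0 together with the array set. A block by replicate number also called these 5 genes (adjusted p = 0.0488 for each), and 0 probes passed in it together with the array set. Within sets A and B the 5 genes gave −0.91 and −1.01, 1.48 and 1.15, −0.49 and −0.93, −0.63 and −0.58, and 0.77 and 0.67, in that order. Cited2 gave 0.14 (adjusted p = 0.859), Lefty1 0.81 (0.442; 0.0354 with array weights), Nodal 0.55 (0.605) and Lefty2 0.38 (0.787).

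Cardiac muscle genes were shifted down on the high-fat diet, by a mean of −0.40 over 27 genes, 22 negative (adjusted p = 5.45e-06; adjusted p = 0.673 with an estimated correlation). None of them passed over all probes in limma, and 5 were lower adjusted over the list alone. The atrial natriuretic peptide gene Nppa gave −1.73 ± 0.46, Nppb −1.38 ± 0.43, the atrial myosin light chain gene Myl7 −0.92 ± 0.25, and Hspb7 −0.58 ± 0.17 (adjusted p = 0.401 for each). The cardiac shift was −0.43 with the array set as a block, −0.56 within set A and −0.31 within set B. Neural tube and brain genes gave −0.19, 18 of 25 negative (adjusted p = 0.00443), Hox genes −0.26, 16 of 22 negative (0.0173), and heat shock genes −0.24, 9 of 11 negative (0.0225), each with an adjusted p of 0.673 with an estimated correlation. Adjusted over the list alone, 3 neural tube genes were lower and 0 in the other pair of lists. Among their members En2 gave −0.91 ± 0.21, Dbx1 −0.89 ± 0.20, Hoxd3 −0.72 ± 0.19 and Hspe1 −0.55 ± 0.31, none of which passed. The shifts were −0.24, −0.23 and −0.14 with the array set as a block, and the heat shock list no longer passed (adjusted p = 0.1). Within sets A and B they were −0.22 and −0.27 for neural tube, −0.18 and −0.28 for Hox, and −0.16 and −0.11 for heat shock genes. These were the 4 lists that passed. Without knockout high-fat replicate 3 the cardiac and heat shock lists passed, and the neural tube (adjusted p = 0.0646) and Hox lists (0.134) did not. With the Y-linked covariate the adjusted p was 0.0667 for the Hox and 0.0915 for the heat shock list. Exact permutation p-values over the list means were 0.0671 for cardiac muscle, 0.0519 for Hox and 0.0476 for heat shock genes (adjusted p = 0.3 for each) and 0.175 for neural tube genes (adjusted p = 0.343). The diet tests, limma included, count each embryo as independent. If the 6 title numbers mark mothers, the diet varied between mothers only, and these p-values may be too small. The yolk sac list, against which the cardiac and neural tube lists ran, gave 0.36 (adjusted p = 0.266; exact permutation p = 0.424), and 0.53 with the array set as a block (adjusted p = 0.00234; adjusted p = 0.654 with an estimated correlation). Since the cardiac and yolk sac list means ran against each other within the groups (r = −0.841), a part of the cardiac shift with diet may follow from differences between embryos in the yolk sac list, and how large a part is left open.

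In wild-type embryos, the high-fat diet changed 0 probes in limma, with 815 at an unadjusted p under 0.05, and 0 of 45 lists. The genes with the smallest p-values, at an adjusted p of 0.830, were Snph with 0.66 ± 0.12, Zfp507 with −0.97 ± 0.21, Igsf21 with 0.78 ± 0.19, Bak1 with 0.54 ± 0.14 and Adgrb2 with 0.57 ± 0.14. With the array set as a block, which holds 1 embryo of a group in each set, 0 probes passed, 952 had an unadjusted p under 0.05, and 3 lists passed. Array weights gave 1466 probes, and 0 together with the array set. Lefty2 gave 1.80 ± 0.93 (2.65 with array weights, adjusted p = 0.0423) and Cited2 −0.27 ± 0.50.

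In knockout embryos, the diet changed 0 probes in limma, with 1205 at an unadjusted p under 0.05, and 1518 with the array set as a block, where 0 passed. Array weights gave 218 probes, and 0 together with the array set. At an adjusted p of 0.704, Crabp1 gave −1.02 ± 0.17, Nckap1l 1.03 ± 0.19, Tob1 −0.95 ± 0.18, Vrtn 1.77 ± 0.33 and Osr2 0.76 ± 0.15. With 1 embryo of a group in each array set, Vrtn gave 2.04 in set A and 1.80 in set B, and Crabp1 −0.98 in each. Lists that passed numbered 13, 2 up and 11 down, and 0 with an estimated correlation, where adjusted p-values were 0.422 to 0.622. Cardiac muscle gave −0.59, 23 of 27 negative (adjusted p = 5.67e-08), and neural tube and brain −0.31, 18 of 25 negative (0.00071), each with an adjusted p of 0.422 with an estimated correlation. Primitive erythroid genes gave 0.51, 18 of 19 positive (adjusted p = 0.0205; adjusted p = 0.622 with an estimated correlation). Adjusted over the list alone, 4 cardiac genes were lower, 5 neural tube genes lower and 1 higher, and 0 erythroid genes passed. Without knockout high-fat replicate 3, 2 lists passed, cardiac muscle and heat shock, and the erythroid list had an adjusted p of 0.777. The Y-linked covariate ended the calls of Hox genes (adjusted p = 0.0541), endothelium (0.147) and heat shock genes (0.0972).

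The interaction asked whether the diet acted differently in knockout and wild-type embryos. In limma 0 probes passed, with 247 at an unadjusted p under 0.05, and with the array set as a block 0 passed, with 543. The genes with the smallest p-values had an adjusted p of 1.00. They were Osr2 with 0.79 ± 0.22, Mdga2 with −0.68 ± 0.19, Slc2a6 with −0.91 ± 0.26, Steap4 with 0.95 ± 0.28 and Rad51b with −0.60 ± 0.18. Lefty2 gave −2.84 ± 1.32, Lefty1 1.25, Nodal −0.20 and Cited2 0.83, also with an adjusted p of 1.00. Of the lists 8 passed, 2 up and 6 down. Cardiac muscle had a mean difference of −0.38, 23 of 27 negative (adjusted p = 0.00175), somites 0.23, 11 of 13 positive (0.0128), and cholesterol synthesis −0.23, 17 of 19 negative (0.00926), each with an adjusted p of 0.545 with an estimated correlation. None of the 8 lists passed with an estimated correlation. With the array set as a block 8 lists passed, and without knockout high-fat replicate 3, 1 list passed, which was none of the 8. With the Y-linked covariate the extracellular matrix list did not pass (adjusted p = 0.0714).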

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

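All tests in this part other than the interaction of diet and genotype were chosen after the results were seen. An embryo far from the others was looked for in 66 sets of 6 embryos of 1 genotype, and 7 such values were found, where chance gives about 1 in 20 sets.

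The Cited2 signal of knockout high-fat replicate 3 was 119.7, against at most 10 in the other 5 knockout embryos. Across the 3 probes its signals were 119.7, 31.2 and 4, with wild-type means of 2811, 389 and 312, so that it held 4.08% ± 0.741, 5.55% ± 1.90 and 2.08% ± 1.60 of the wild-type signal (standard error). The highest share, 5.55%, argues against an embryo that was heterozygous or wild-type under a wrong label. Probes undetected on every array were brighter there than on the other knockout arrays by a mean signal of 0.00203. Such probes are chosen against the negative controls of each array, and their mean signal was −1.36 to −0.84 on every array. They can therefore not tell whether the background was raised. The 3 shares differed by at most 1.40 standard errors of their difference, so a small admixture of RNA from tissue expressing Cited2, about 3.93% of the wild-type level, may account for the signal. This embryo also stood apart on the second principal component, at −42.3 against −16.2 to 16.1 on the other arrays. Its yolk sac endoderm (1.46), primitive erythroid (0.823) and trophoblast (0.678) list means were the highest of the 12. Those of allantois (0.067), amnion and surface ectoderm (−0.041) and maternal decidua (−0.275) were not. Whether these share a source with the Cited2 signal was not tested, nor was any biological explanation.

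Of the 9 protein-coding genes other than Cited2 that passed in the averaged genotype comparison, 4 lay within 50 genes of Cited2, where the embryos' DNA around the deletion is inherited with it. Chance placement in the gene order is argued against by Fisher's exact p = 3.9e-08, although the window was set after the genes had been seen. A sequence difference under the probe lowers the signal, so a mismatch in the knockout's DNA alone could not make Lats1 and Adat2 higher. This follows from their direction and was no separate test. A mismatch in the wild-type DNA would act the other way and was not tested, and each was read at 1 tested probe. A mismatch in the knockout's DNA stays open for Hebp2, whose other probe gave 0.05. For E030030I06Rik it would have to lie under each of 3 probes (the other 2 gave −0.88 and −0.79). A strain variant in the DNA linked to the deletion could change these genes as well as the loss of Cited2 could. These cannot be told apart, because the labels separate the genotype at Cited2 from that of the linked DNA in 0 embryos.

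Yolk sac endoderm markers were higher in knockout embryos by a mean of 0.62 on the log2 scale, with shifts of 0.02 in array set A and 1.64 in set B, and by 0.37 without knockout high-fat replicate 3. Variation between embryos regardless of genotype is not excluded (exact permutation p = 0.173 over the 12 list means, higher than the wild-type median in 5 of 6 knockout embryos). Yolk sac left on some embryos after dissection might raise these markers, and would bring primitive blood cells along. The yolk sac and primitive erythroid lists, which share 0 genes, had r = 0.529 over the 12 embryos as deviations from group means (permutation p = 0.0782; rho = 0.490, p = 0.108; r = 0.515 without the 2 farthest embryos; 0.416 and 0.599 in sets A and B), which leaves this open. Deviations from group means hold no genotype difference, so they bear on differences between embryos only. Between the genotypes the erythroid list went the other way, at −0.10 ± 0.51 in knockout and 0.10 ± 0.48 in wild-type embryos (SD, n = 6). That difference lay within the spread (exact permutation p = 0.489). A change of the endoderm itself in knockout embryos also stays open and was not tested.

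The unnamed probe ILMN_1239542, higher in knockout embryos, was 6.69 in wild-type high-fat replicate 3, where the next wild-type value was 4.35, and the cause was not tested. Among the named genes, Csmd3 was 4.72 in wild-type control replicate 2, where the next wild-type value was 4.60. Cldn10 was 7.24 in knockout high-fat replicate 3, where the next knockout value was 7.60. Flrt1 at its dimmer probe was 4.42 in knockout high-fat replicate 2, where the next was 4.82. Lefty2 was 7.66 in knockout control replicate 2, where the next was 5.13. The p53 list mean was 0.154 in knockout control replicate 2, where the next was 0.0486.

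The diet effect differed between the genotypes in 8 lists at the preset correlation, none of which passed with an estimated correlation (adjusted p = 0.545 to 0.626). The adjusted p of the interaction was 0.00175 for cardiac muscle, 0.00297 for maternal decidua, 0.00926 for cholesterol synthesis, 0.0128 for somites and 0.017 for hypoxia targets. It was 0.0312 for primitive erythroid genes and 0.0425 for both neural crest and extracellular matrix. Mean differences were −0.34 for decidua, −0.17 for hypoxia targets, 0.46 for erythroid genes, −0.32 for neural crest and −0.17 for extracellular matrix. Without knockout high-fat replicate 3, 0 of these 8 lists passed.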

How the results depend on the processing

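The alternatives with array set or bead variation, and lists without knockout high-fat replicate 3, were chosen after the data were seen, and the others before. Over all alternatives, 575 of 661 values of named genes that passed kept their call and 86 lost it, none with a reversed direction. Of 3312 values of named genes that did not pass, 94 passed, and of 567 values of lists that passed, 436 kept the call and 131 lost it. The cause was not tested except where stated. In the averaged genotype effect 14 probes passed, against 20 with median scaling, 18 with cyclic loess and 19 with the authors' table. Of the 19595 tested probes, 14496 were detected on all 12 arrays.

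Detection on all 12 arrays gave 4 probes for the averaged genotype effect, 2 on the control diet and 0 in limma on the high-fat diet, where probes dim in knockout embryos are no longer tested. No filter gave 5 on the control diet, over more probes tested. On the high-fat diet the authors' table gave 5, and an intensity trend with robust variances gave 5. Array weights gave 120 (averaged genotype), 6128 (averaged diet), 16 (genotype, control diet), 1325 (genotype, high-fat diet), 1466 (diet, wild type) and 218 (diet, knockout). The highest weight was 7.43, for wild-type high-fat replicate 2. Weights together with the array set gave 30 for the averaged genotype effect, 22 on the control diet, 8 on the high-fat diet and 0 for the averaged diet effect. The array set as a block gave 27, 17 and 6 for the 3 genotype effects, and bead variation as a covariate gave 35, 16 and 10. The Y-linked covariate gave 5 on the control diet.

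Each title number joined 1 knockout and 1 wild-type embryo on the same diet. The title numbers and replicate numbers were not taken as pairs, since not every pair correlated above 0.1. Of the title-number pairs 2 of 6 did, and of the replicate-number pairs 13 of 18, and 3 arrays correlated best with their own title number. This cutoff does not show that the embryos were unrelated. If the number marks a mother, the diet comparisons count embryos of 1 mother as independent. Only 2 of the 6 title-number pairs share an array set. With the array set removed, 4 of 6 title-number pairs (from −0.0387 to 0.534) and 1 of 18 replicate-number pairs correlated above 0.1, so a relation between embryos of the same title number stays open. A replicate block by title number with the array set gave 18, 9 and 4 probes for the 3 genotype effects, with an adjusted p of 0.0879 for Meox1 and 0.0579 for Csmd3 in the averaged effect and of 0.126 for Lats1 and 0.143 for Flrt1 at its dimmer probe on the control diet. A replicate block by title number gave 7 probes for the averaged genotype effect and 4 on the control diet, and as a random block 5 on the control diet. In the fixed block the adjusted p was 0.0673 for Lats1, 0.238 for Csmd3, 0.0523 for Hebp2, 0.257 for Cldn10, 0.400 for Meox1 and 0.264 for Flrt1 at its dimmer probe, over ranges of 0.000345 to 0.0673, 0.000667 to 0.238, 3.4e-05 to 0.0523, 0.000133 to 0.257, 0.000668 to 0.400 and 0.000134 to 0.264. On the control diet it was 0.370 for Lats1, 0.225 for Adat2, 0.3 for Hebp2 and 0.924 for Flrt1 at its dimmer probe. A replicate block by replicate number gave 24 (averaged genotype), 338 (averaged diet) and 5 (genotype, high-fat diet), with an adjusted p of 0.0488 for Zfp507, Vrtn, Tob1, Crabp1 and Nckap1l under averaged diet, and with the array set 23 and 0 for the averaged effects. High-fat replicate 2 lies in array set A and control replicate 2 in set B, so this block alone leaves the set in the diet effect.

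Of the lists, an estimated correlation left 1 for the averaged genotype effect, 1 on the control diet, and 0 on the high-fat diet, for the averaged diet effect, for diet in knockout embryos and for the interaction. The Y-linked covariate gave 9 for the averaged genotype effect, 8 of them among the 14, and 6 on the high-fat diet. The array set as a block gave 8 for the averaged diet effect and 3 for diet in wild-type embryos. Without knockout high-fat replicate 3 the counts were 14, 13 and 5 for the averaged, control-diet and high-fat genotype effects, 2, 0 and 2 for diet averaged, in wild-type and in knockout embryos, and 1 for the interaction. Leaving out 1 embryo at a time gave 12 to 19 probes for the averaged genotype effect, 3 to 12 on the control diet, 3 to 8 on the high-fat diet, and 0 to 0 for the other comparisons.

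Directions reversed in 24 values of 8 results, none of which had passed or passed then (lowest adjusted p 0.361). With array weights Cited2 gave −0.10 for averaged diet, Lefty1 −0.10 for diet in wild type and Nodal 0.0054 for the interaction. Weights with the array set gave Nodal 0.35 for the interaction and Lefty2 −0.18 for averaged diet and −0.37 for genotype on the control diet. The Y-linked covariate gave Lefty2 −0.015 and −0.16 in those comparisons, and bead variation gave Lefty2 −0.10 for genotype on the control diet and Cited2 0.25 for diet in wild type. The replicate block by replicate number with the array set gave Lefty1 −0.16 for diet in wild type. Leaving out 1 embryo gave ranges of −0.43 to 0.93 for Nodal under diet in knockouts, −1.08 to 0.41 for Nodal in the interaction, −0.023 to 0.86 for Lefty2 and −0.25 to 0.36 for Cited2 under averaged diet. They were −0.047 to 0.32 for Lefty1 under diet in wild type, −0.76 to 0.84 for Lefty2 under genotype on the control diet, and −0.23 to 1.00 for Cited2 under diet in knockouts. A slide block was not run, because the slides are not given in the sources used here.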

Other observations

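All tests in this part other than the list tests and the Y-linked covariate were chosen after the results were seen. A block for array set brought further somite and brain regulators past the threshold in the averaged genotype comparison. Uncx, a homeobox gene of the posterior somite, had a log2 fold change of −0.96 and an adjusted p of 0.0191, with 0.00135 to 0.400 over the alternatives. Tcf15, which acts in somite epithelium, had −0.67 and 0.0454, over a range of 0.0105 to 1.00. En1, the homeobox relative of En2, had −1.36 and 0.0415, over a range of 0.00129 to 0.436. The genes named here outside the rule are Rab32, a small GTPase of membrane traffic, with −1.18 (adjusted p = 0.0348), Sash1 with 0.98 (0.0466) and 4930426D05Rik with −0.77 (0.00344), chosen after their values were seen.

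The second heart field and outflow tract list did not pass (mean −0.10 over 16 genes, adjusted p = 0.0572; adjusted p = 0.243 with an estimated correlation), while 3 members were lower adjusted over the list alone. Its mean per embryo was −0.05 ± 0.05 in knockout and 0.05 ± 0.04 in wild-type embryos (SD, n = 6; exact permutation p = 0.00216, the smallest the splits allow, adjusted p = 0.0325). Housekeeping lists stayed flat, with means of −0.01 over 53 ribosomal protein genes (adjusted p = 0.866) and 0.02 over 62 oxidative phosphorylation genes (0.566). Fatty acid oxidation gave 0.01 over 24 genes (adjusted p = 0.704) and fatty acid synthesis 0.06 over 18 (0.105). Markers of trophoblast (0.22 over 7 genes, adjusted p = 0.365), allantois (0.07 over 14, 0.218) and maternal decidua (−0.04 over 11, 0.704) did not pass either.

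The Y-linked gene Eif2s3y differed between embryos, with log2 signals of 5.62, 6.07 and 4.41 in control-diet knockout replicates 1 to 3 and 4.39, 4.54 and 4.30 in the high-fat knockout replicates. In wild-type replicates 1 to 3 it was 4.54, 6.65 and 7.10 on the control diet and 5.39, 4.34 and 6.45 on the high-fat diet. All high-fat knockout embryos thus lay at 4.30 to 4.54, while each other group reached 6.07 or more. If this signal marks sex, sex overlapped in part with the high-fat knockout group. This touches the genotype effect on the high-fat diet, the diet effect in knockout embryos and the interaction, and also the averaged effects.

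Other splits of the embryos tested whether the groups as labelled gave more calls than chance. For the averaged genotype effect, 1 of 100 splits, the real one, gave as many as 14 probes, with 6 as the highest of the others. As many as 14 lists were given by 3 of 100, with 17 as the highest. Both shares lie under 0.05 among the splits drawn, which were a part of those possible. The 14 probes include those of Cited2, the deleted gene, and of genes beside it. The probe count is therefore no test of changes away from the deletion. Of the 40 splits that divide each array set evenly, as the real groups do, 1 gave as many probes (highest other 0) and 3 as many lists, so among these chance is not excluded for the lists. For the averaged diet effect, 64 of 100 splits gave at least the 4 lists of the real groups, with 20 as the highest, so chance is not excluded for the lists. The real groups gave 0 probes, which 100 of 100 splits reach, so the probe count tests nothing. A split that followed the array sets exactly gave 6684 probes, and a split with 5 set B arrays on one side gave 2974, which is the structure of the samples already seen in the array sets and no further test of it. Blocked by array set, the real diet groups gave 0 probes in limma and 8 lists. For the interaction, 27 of 100 splits gave at least the 8 lists, with 18 as the highest, so chance is not excluded for the lists, while the real count of 0 probes, reached by 100 of 100 splits (highest other 280), tests nothing.

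The comparisons of 3 against 3 embryos have 10 splits, too few for a share under 0.05. For the genotype effect on the control diet, 1 of 10 splits gave as many as 8 probes (highest other 0) and 1 of 10 as many as 13 lists (highest other 9). On the high-fat diet these were 1 of 10 for 3 probes (highest other 0) and 1 of 10 for 11 lists (highest other 10). For the diet effect in wild-type embryos, 10 of 10 splits gave at least 0 probes (highest other 0) and 10 of 10 at least 0 lists (highest other 8). In knockout embryos 10 of 10 gave at least 0 probes (highest other 1) and 2 of 10 at least 13 lists (highest other 15).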
